A study of Homo sapiens with 6 samples.

How the data were processed

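RNA-seq libraries of ACHN cells, 3 control and 3 treated with curcumol, were compared. The labels' protocols say that poly(A) RNA was selected, fragmented and sequenced in pairs on an Illumina instrument. They call the control a vehicle control, while the design text of the series says that it received no drug, so the vehicle is uncertain. Dose and time are not given in the sources used here. The authors deposited 1 table of raw counts, whole numbers per Ensembl gene and library that were not normalized. The genome build is GRCh38 (hg38), per the submitters' processing notes. The aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here. The 58735 gene identifiers in the table are the same as those of GENCODE 29 (Ensembl 94, GRCh38), which gave coordinates, exon overlaps, exon lengths and GC content. Exon length is that of all annotated exons of a gene joined, which can exceed the length of its mRNA. How the counting tool treated reads that fit several genes is not known, which affects near-identical genes such as HSPA1A and HSPA1B, families with processed pseudogenes and genes that overlap.

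Samples were grouped by their labels, which describe independent biological replicates. Totals ran from 16962012 to 17827433 counts per library, and 30878 genes had at least 1 count. Log2 CPM within a group correlated at 0.988 to 0.992 across genes, and pairs of libraries of a group differed beyond sampling noise (chi-square per degree of freedom 3.68 to 8.82), so none was counted as a repeat of another. The common biological coefficient of variation was 0.0731. The number of libraries per group, 3, limits the precision more than depth does for abundant genes, and counts near 0 carry counting error.

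The test was fixed before the data were examined. Genes were filtered with filterByExpr by group (15160 kept), scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust, both directions) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are scaled by TMM factors and given as mean ± SD. The 33 gene lists were fixed before the data were examined, and 636 of their 637 entries were matched to an identifier, 22 of them through a current symbol. Lists with at least 5 tested members (29) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over these lists. The remaining 4 lists, markers of other cell types, had too few tested members. The integrated stress response list was kept as fixed although 1 entry, DDR2, does not belong to it, and was tested again without it.

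Named genes followed a rule fixed in advance. It took the 10 largest rises and the 10 largest falls among genes that passed, had a symbol, had a mean of at least 100 counts and were separated between the groups, and 6 glycolysis genes whatever their result. It also took the 3 members with the smallest p of the glycolysis list and of each list called by camera, and the first member of each other list if it passed. XIST and Y-linked genes were left out, and some genes that the rule takes are not reported here. List members outside the rule, among them HSPD1, COL3A1, PTPRC and DUSP4, were named after their values were seen, also where this is not repeated.

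The code was tested on simulated counts in which 200 genes were set to change, not all of them among the 14817 genes run. In the data 79.7% of tested genes were called, so the simulation does not test the scaling under so wide a change. Of the changed genes that were run, edgeR recovered 28% of 50 at 1.25-fold and 65.3% of 49 at 1.5-fold. It recovered 85.1% of 47 at 2-fold and 95.7% of 47 at 4-fold, with 0 wrong signs and 9.66% false calls. Camera called 0 of 50 unchanged simulated lists. The simulated genes were drawn independently, so this says nothing about false calls for lists with correlated members. The estimated correlation was 0.637 for the ribosomal protein list. Alternatives were DESeq2 1.42.0, limma-voom, DESeq2-type size factors, library totals, 2 other filters (none, and a mean of at least 1 CPM and 50 counts), the replicate number as a block, a test against a 1.2-fold change, each library left out in turn, an estimated correlation and fry. Added after seeing the data were fits without the 50 most abundant genes, with offsets for exon length or GC content (a spline with 5 degrees of freedom per library) and with DDR2 left out of its list.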

Results

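The series measured poly(A)-selected RNA in ACHN cells, an established human renal carcinoma line that the submitters describe as clear cell renal cell carcinoma. Curcumol is a sesquiterpenoid found in the rhizome oil of Curcuma species. The stated purpose was to learn how curcumol acts on glycolysis and on malignant behaviour in these cells. There were 3 control and 3 curcumol libraries, described as independent biological replicates. The dose and the time of exposure are not given in the sources used here. The libraries held 16962012 to 17827433 counts each, and 15160 genes had enough counts to be tested.

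Curcumol-treated cells had higher mRNA of heat shock genes and NRF2 targets, and lower mRNA of S phase genes, by the counts and tests of the lists given below. These list calls, made by camera with a preset correlation, were lost with an estimated correlation (adjusted p = 0.427, 0.328 and 0.328 with an estimated correlation). Of the 15160 genes tested, 5967 were higher and 6109 were lower in curcumol (edgeR quasi-likelihood test, adjusted p under 0.05). Together these were 12076 genes, or 79.7% of those tested. A change of at least 2-fold was seen for 3223 genes that rose and 3508 that fell, and one of at least 4-fold for 1182 and 1241. The 3 curcumol libraries lay all above or all below the 3 control libraries for 12278 genes (81%), where chance gives 10%. Each gene named below as risen or fallen was separated in this way, unless it is said to differ. Counts of list members that rose or fell rest on the adjusted p alone and include some that were not separated.

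The largest rise was that of HSPA6, a stress-inducible HSP70 chaperone (ENSG00000173110, chromosome 1, 161524540 to 161526910, GRCh38), from 0.575 ± 0.235 CPM in control to 128 ± 11.7 CPM in curcumol (SD, n = 3). Its log2 fold change was 7.77 ± 0.15 (SE, edgeR adjusted p = 2.47e-20). HSPA1A (6.59 ± 0.11) and HSPA1B (6.43 ± 0.09), also inducible HSP70 genes, lie close to each other on chromosome 6 and are nearly identical, so the division of counts between them is uncertain. HMOX1, heme oxygenase 1 (ENSG00000100292, chromosome 22, 35380361 to 35394214), rose from 25.8 ± 4.36 to 1261 ± 146 CPM (SD, n = 3), a log2 fold change of 5.61 ± 0.14 (SE, edgeR adjusted p = 6.03e-10). FOSB (5.51) and FOS (5.33), subunits of the AP-1 transcription factor, and AOC3 (5.21), a membrane amine oxidase, rose as well. LINC00324, a long noncoding RNA, rose by a log2 fold change of 5.37, and LSMEM1 by 5.22. TBR1, a transcription factor of the developing cortex, had 0, 0 and 5 counts in control and 173, 211 and 273 in curcumol, and its fitted log2 fold change of 7.20 depends on the prior count and was 10.88 without control replicate 3.

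The largest fall was that of SFXN2, a mitochondrial sideroflexin (ENSG00000156398, chromosome 10, 102714538 to 102743492), from 32.6 ± 2.34 to 0.401 ± 0.0408 CPM (SD, n = 3), a log2 fold change of -6.32 ± 0.18 (SE, edgeR adjusted p = 9.63e-18). The neutrophil chemokines CXCL2 (-5.19 ± 0.16) and CXCL1 (-4.93 ± 0.15) fell. So did ITGB6 (-4.61), the beta subunit of an epithelial integrin, CLDN11 (-4.30), a tight junction claudin, and MEGF6 (-4.36). LFNG, a glycosyltransferase that modifies Notch receptors, went from 209 ± 27.9 to 8.77 ± 1.23 CPM (SD, n = 3) with a log2 fold change of -4.57. PADI2, a peptidylarginine deiminase, changed by -4.39 and the long noncoding RNA CASC19 by -5.01. SPC24, a kinetochore gene, changed by -4.64. LSMEM1 shares 157 exonic bases with IFRD1 on its own strand. The counting is not stated to use strand, so reads from exons that overlap between genes, as some of SPC24 do, cannot be assigned.

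**Figure D1:**
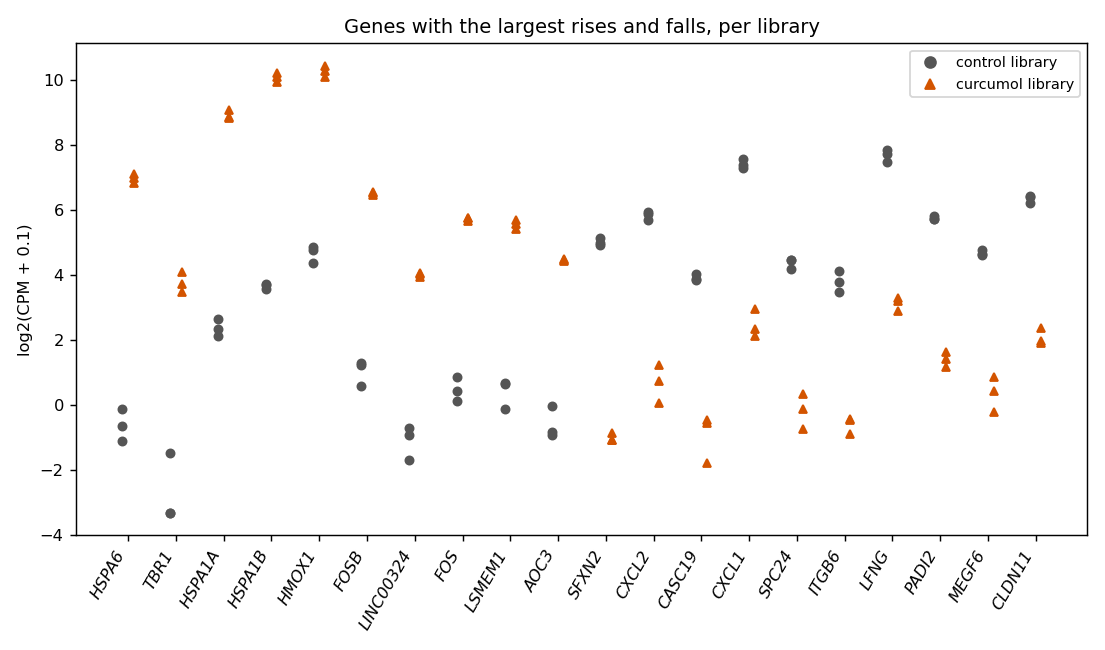
The 10 largest rises and the 10 largest falls, chosen by the fixed rule, as log2(CPM + 0.1) in each library (vertical axis); circles are the 3 control libraries and triangles the 3 curcumol libraries. For each gene the 3 curcumol libraries lie on one side of the 3 control libraries, and HMOX1 stands at 25.8 CPM in control and 1261 CPM in curcumol on average.

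For glycolysis, the question the series names, 18 of the 24 genes of the list rose, 4 fell and 2 did not pass (edgeR), and the counts adjusted over the list alone were also 18 and 4. The median log2 fold change was 0.89, and the list was higher than other genes by camera (adjusted p = 0.00642), a call that was lost with an estimated correlation (adjusted p = 0.559 with an estimated correlation). SLC2A3, the glucose transporter GLUT3 (ENSG00000059804, chromosome 12, 7919230 to 7936275), rose most, from 13.6 ± 2.36 to 210 ± 7.04 CPM (SD, n = 3), with a log2 fold change of 3.94 ± 0.09 (SE, edgeR adjusted p = 8.03e-19). HK2, a hexokinase that starts glucose breakdown, rose by 1.53 ± 0.06, PFKFB3, which makes an activator of phosphofructokinase, by 1.31 ± 0.06, and PGK1, phosphoglycerate kinase, by 1.41 ± 0.06. The monocarboxylate transporters moved apart, since SLC16A1 (MCT1) rose by 1.52 ± 0.05 and SLC16A3 (MCT4) changed by -2.28 ± 0.21. SLC16A3 had few counts, with 158, 217 and 173 in control and 38, 23 and 32 in curcumol, and shares 482 exonic bases with CSNK1D on the other strand. The 3 phosphofructokinase genes fell, named here after their values were seen: PFKL by a log2 change of -1.25, PFKM of -0.75 and PFKP of -0.33. With a GC offset 18 members of the list rose and 3 fell, SLC16A3 among them, so not all phosphofructokinase genes kept their fall.

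The changes of the other fixed glycolysis genes were smaller. SLC2A1 (GLUT1) rose by 0.45 ± 0.07, pyruvate kinase PKM by 0.28 ± 0.06 and lactate dehydrogenase LDHA by 0.27 ± 0.07 on the log2 scale (SE). Scaling by library totals alone moved the median of all genes from -0.02 to -0.28. Under that scaling SLC2A1 stood at 0.19, PKM at 0.02 (edgeR adjusted p = 0.783) and LDHA at 0.00 (edgeR adjusted p = 0.968), and 15 members of the list rose and 5 fell. Over all genes, 4818 were then higher and 7372 lower. With an offset for GC content, LDHA stood at 0.02 (edgeR adjusted p = 0.794), SLC2A1 at 0.79 and PKM at 0.54.

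**Figure D2:**
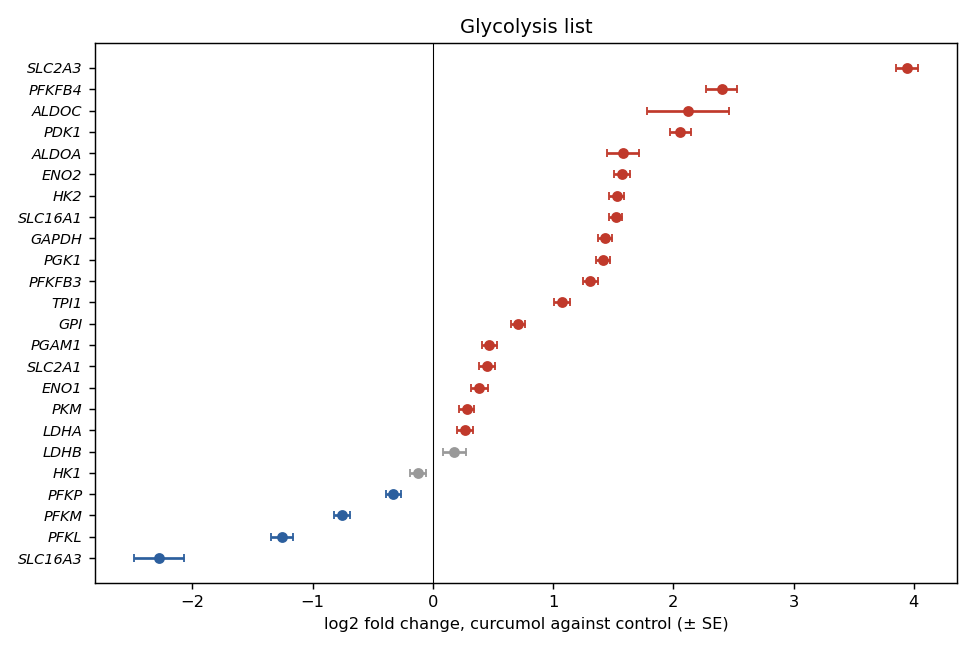
Log2 fold change, curcumol against control, of the 24 genes of the glycolysis list (points) with the standard error of the edgeR fit (bars); red points rose, blue points fell and grey points did not pass at an adjusted p of 0.05. The values run from -2.28 for SLC16A3 to 3.94 for SLC2A3, and those of PKM and LDHA do not pass when library totals alone set the scale.

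Genes induced by low oxygen were higher in curcumol. Of 19 tested members of the hypoxia list, 15 rose and 2 fell, with a median log2 fold change of 1.39 (camera adjusted p = 0.000397, and adjusted p = 0.328 with an estimated correlation). NDRG1 rose from 54.3 ± 1.36 to 663 ± 28.7 CPM (SD, n = 3), a log2 fold change of 3.61 ± 0.06. BNIP3 (2.87 ± 0.06) and BNIP3L (3.27 ± 0.07), receptors for the removal of mitochondria by autophagy, rose as well.

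Stress response lists rose. In the heat shock list 15 of 16 genes rose and 0 fell, with a median of 1.77 (camera adjusted p = 8.48e-06, and adjusted p = 0.427 with an estimated correlation). HSPA1B had the smallest p, followed by the co-chaperones BAG3 (3.83 ± 0.07) and DNAJB1 (3.89 ± 0.07). HSPD1, the mitochondrial HSP60, stood at -0.06 and did not pass, and under scaling by library totals 1 member of the list fell. Of 19 targets of NRF2, the regulator of antioxidant genes, 17 rose and 2 fell, with a median of 1.66 (camera adjusted p = 3.46e-05, and adjusted p = 0.328 with an estimated correlation). Ferritin light chain FTL went from 656 ± 1.42 to 5691 ± 372 CPM (SD, n = 3), a log2 fold change of 3.12 ± 0.06, OSGIN1 rose by 3.81 ± 0.08 and thioredoxin reductase TXNRD1 by 1.98 ± 0.05. All 22 genes of the autophagy and lysosome list rose, with a median of 1.24 (camera adjusted p = 1.87e-06, and adjusted p = 0.18 with an estimated correlation), and 20 of them rose under scaling by library totals. GABARAPL1 (4.60 ± 0.08) and MAP1LC3B (3.72 ± 0.07) encode autophagosome proteins, and GLA (2.60 ± 0.07) encodes a lysosomal galactosidase.

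Of 19 genes of the integrated stress response list, 13 rose and 5 fell, with a median of 1.05 (camera adjusted p = 0.0285, and adjusted p = 0.328 with an estimated correlation). PPP1R15A, which directs dephosphorylation of eIF2 alpha, rose from 59.1 ± 6.68 to 1790 ± 73.2 CPM (SD, n = 3), a log2 fold change of 4.92 ± 0.08. The transcription factor genes ATF3 (3.53 ± 0.07) and DDIT3 (3.33 ± 0.08) rose, and DDIT3 shares 355 exonic bases with MARS on the other strand. The list as fixed holds DDR2, a collagen receptor that is not an established target of ATF4 and that rose by 4.46. Without DDR2, an alternative chosen after its value was seen, the median was 0.83 (camera adjusted p = 0.0454, and adjusted p = 0.384 with an estimated correlation). Endoplasmic reticulum chaperone genes went both ways, with 11 of 18 higher and 6 lower (camera adjusted p = 0.27). DNAJB9, a target of the unfolded protein response, rose by 3.84 ± 0.08 and shares 183 exonic bases with THAP5 on the other strand.

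In the S phase list 21 of 24 genes fell and 1 rose, with a median of -1.20 (camera adjusted p = 2.75e-05, and adjusted p = 0.328 with an estimated correlation). The replicative helicase genes MCM5 (-2.56 ± 0.09), MCM6 (-1.87 ± 0.07) and MCM4 (-1.75 ± 0.06) fell, and MCM5 went from 140 ± 5.33 to 23.7 ± 3.39 CPM (SD, n = 3). The member that rose was CDC6 (0.18), a replication licensing factor named after its value was seen, and 0 members rose under scaling by library totals. Of 20 mitosis genes 13 fell and 2 rose (median -0.55, camera adjusted p = 0.0572). That list passed without control replicate 2 (camera adjusted p = 0.0438), with library totals (0.0468), with an exon length offset (0.0461) and with a GC offset (0.0116), but not with an estimated correlation (adjusted p = 0.47 with an estimated correlation). CCNA2, cyclin A2, changed by -2.28 ± 0.07 and shares 254 exonic bases with EXOSC9 on the other strand. Among p53 targets 12 of 20 rose and 5 fell (camera adjusted p = 0.118), with GADD45A up from 70.1 ± 1.83 to 949 ± 39.5 CPM (SD, n = 3). Among regulators of apoptosis 11 of 19 rose and 5 fell (camera adjusted p = 0.224), and PMAIP1, which encodes the BH3 protein NOXA, rose by 2.22 ± 0.07.

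Other metabolic lists were mixed. In the amino acid and serine list 14 of 20 genes fell and 3 rose, with a median of -0.82 (camera adjusted p = 0.0281, and adjusted p = 0.47 with an estimated correlation). PYCR1 of proline synthesis (-2.21 ± 0.09) and the folate enzyme MTHFD1 (-1.79 ± 0.07) fell, and the neutral amino acid transporter SLC38A2 rose by 2.25 ± 0.07. In the TCA cycle list 10 of 20 fell and 7 rose (camera adjusted p = 0.446), with SUCLG2 at -1.80 ± 0.08. In the pentose phosphate list 8 of 12 fell and 3 rose (camera adjusted p = 0.241), with H6PD of the endoplasmic reticulum at -3.35 ± 0.15. Of 22 nuclear genes for oxidative phosphorylation 9 rose and 8 fell (camera adjusted p = 0.832), with the complex I gene NDUFV1 at -1.42 ± 0.08, or -0.85 with a GC offset. With library totals 6 rose and 12 fell, and with a GC offset 11 rose and 6 fell. Their median of -0.07, mean of 0.03 and upward camera direction differ in sign.

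Of 13 mRNAs of the mitochondrial genome 6 rose and 0 fell (median 0.08, camera adjusted p = 0.27), but 3 rose and 6 fell under scaling by library totals (median -0.19), and 2 rose and 2 fell with a GC offset. MT-ND1 rose by 0.80 ± 0.07. The fatty acid list had 10 of 20 lower and 8 higher (camera adjusted p = 0.589), or 11 lower and 4 higher with library totals, and FASN, fatty acid synthase, went from 452 ± 11.9 to 65.6 ± 2.45 CPM (SD, n = 3), a log2 fold change of -2.79 ± 0.06. The cholesterol synthesis list had 11 of 21 higher and 5 lower (camera adjusted p = 0.119) and passed with a GC offset (camera adjusted p = 0.0372), but not with an estimated correlation (adjusted p = 0.559 with an estimated correlation). Its member IDI1 rose by 2.58 ± 0.08.

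Lists that bear on malignant behaviour and on cell identity held members that went both ways. In the mesenchymal and invasion list 12 of 20 genes fell and 5 rose (camera adjusted p = 0.158). The transcription factors ZEB1 (2.24), ZEB2 (1.79) and SNAI1 (2.88), known to repress epithelial genes and named after their values were seen, rose. In the epithelial list 10 of 16 fell and 1 rose (camera adjusted p = 0.118), with CLDN1, a tight junction gene, at -1.99 ± 0.06, and with a GC offset 6 fell and 3 rose. Of 9 renal tubule genes 5 fell and 4 rose (camera adjusted p = 0.734), and the median of -0.59 and the mean of 0.15 differ in sign. Of 16 targets of YAP 11 fell and 5 rose (camera adjusted p = 0.158), and ANKRD1, the member with the smallest p, rose by 4.39 ± 0.11.

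In the list of NF-kB targets and cytokines 11 of 18 genes fell and 2 rose, with a median of -0.49 (camera adjusted p = 0.0385, and adjusted p = 0.459 with an estimated correlation). This call was also lost without curcumol replicate 1 (camera adjusted p = 0.0645) and with a GC offset (0.147), and the median was -0.32 without curcumol replicate 2 and -0.76 with library totals. Besides CXCL2 and CXCL1, IL6 went from 87.2 ± 9.97 to 10.5 ± 0.521 CPM (SD, n = 3), a log2 fold change of -3.05 ± 0.10, and NFKBIA, which encodes an inhibitor of NF-kB, changed by -1.89 ± 0.09. The interferon list had 8 of 17 higher and 7 lower (camera adjusted p = 0.667). The xenobiotic list had 4 of 10 higher and 3 lower (camera adjusted p = 0.734). Its median of -0.31 and mean of -0.14 were below 0 where camera gave an upward direction, and the median was 0.28 without control replicate 3. ABCB1, a drug efflux pump, rose by 3.36 ± 0.13. Of 18 immediate early genes 11 rose and 4 fell (median 1.22, camera adjusted p = 0.0629). That list passed without control replicate 2 (camera adjusted p = 0.0438), without curcumol replicate 1 (0.0423), with library totals (0.0468) and with a GC offset (0.00983), but not with an estimated correlation (adjusted p = 0.459 with an estimated correlation).

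Ribosomal protein mRNAs and histone mRNAs were higher. Of 36 ribosomal protein genes 34 rose and 0 fell, or 35 adjusted over the list alone, with a median of 0.94 (camera adjusted p = 9.42e-08, and adjusted p = 0.47 with an estimated correlation). RPL7 rose from 702 ± 25.8 to 1608 ± 61.9 CPM (SD, n = 3), RPL37 by 1.29 ± 0.07 and RPLP2 by 1.02 ± 0.05, and genes of this family share reads with processed pseudogenes. With library totals 34 rose and 2 fell. With a GC offset RPL7 stood at 0.69 and RPLP2 at 1.65, against 1.195 and 1.02 without it. In the ribosome biogenesis list 10 of 20 fell and 6 rose (camera adjusted p = 0.385), with BOP1 at -2.29 ± 0.10, or -1.50 with a GC offset. With library totals 14 of these fell and 1 rose. All 11 tested replication-dependent histone genes rose, with a median of 3.37 (camera adjusted p = 0.000182, and adjusted p = 0.18 with an estimated correlation). The other 8 members had too few counts to be tested, and held 80 counts in control and 81 in curcumol. H2AC6 (3.37 ± 0.14), H2BC5 (3.64 ± 0.15) and H1-2 (3.29 ± 0.15) were low in control, and H2AC6 went from 3.53 ± 0.883 to 36.7 ± 0.712 CPM (SD, n = 3). Counts of the members adjusted over the list alone equalled those over all genes in every list but that of the ribosomal proteins.

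**Figure D3:**
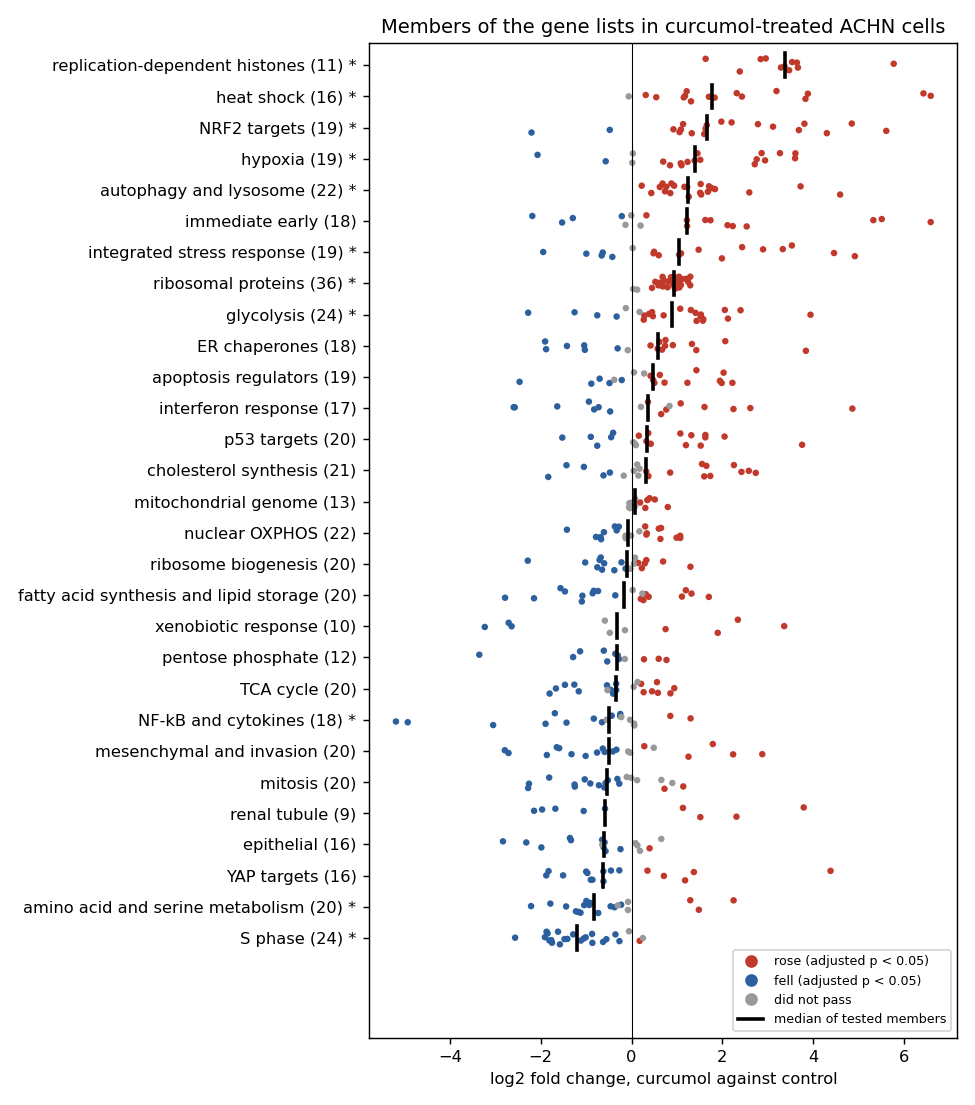
Log2 fold change, curcumol against control, of each tested member (points) of the 29 gene lists with at least 5 tested members, with the number tested in brackets; black bars are medians and an asterisk marks the 11 lists called by camera with a preset correlation. Red points rose, blue points fell and grey points did not pass at an edgeR adjusted p of 0.05; medians run from -1.20 for S phase to 3.37 for histones, and that of the mitochondrial genome is below 0 under scaling by library totals.

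Several measures of the libraries moved with the treatment. The 10 most abundant genes took 6.17% ± 0.254 of counts in control and 8.91% ± 0.31 in curcumol, and ribosomal RNA of the mitochondrion took 0.939% ± 0.0238 and 1.62% ± 0.0607 (SD, n = 3). TMM factors were 1.10 ± 0.00702 in control and 0.912 ± 0.0103 in curcumol. Log2 fold change fell with GC content across 15154 genes (Spearman rho -0.34), where genes are not independent replicates, and rho with exon length was -0.048. In the third of genes with the lowest GC content 2829 rose and 1196 fell, and in the third with the highest 1163 rose and 2919 fell. With a GC offset 1470 of the called genes lost their call and 380 had the opposite sign.

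Of the markers of other cell types THY1, on the fibroblast list, was abundant, at 156 ± 4.39 CPM in control and 31.1 ± 2.35 CPM in curcumol (SD, n = 3), a log2 fold change of -2.33 ± 0.07. COL1A2, LUM, DCN and PDGFRA, fibroblast markers singled out after their values were seen, summed to 111 counts in curcumol replicate 2 and to at most 2 in any other library. Without that replicate 11927 genes passed. COL3A1 had 0 counts in each control library and 28, 58 and 23 in curcumol. CD14, a monocyte marker, had 0, 3 and 2 counts in control and 71, 77 and 67 in curcumol, while PTPRC, the leukocyte antigen CD45, had 0 in each control library and 5, 8 and 7 in curcumol. The endothelial marker ESAM stood at 0.61 ± 0.20 and MITF, from the list of other cell lines, at 0.58 ± 0.10. ESAM did not pass with library totals (0.35, edgeR adjusted p = 0.113), and MITF, at 0.31 with library totals, did not pass with a GC offset (0.17, edgeR adjusted p = 0.116).

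Fold changes are relative to the other genes of a library, and with most genes changed and no added standard a change in total RNA per cell cannot be seen. The list calls rest on a preset correlation between genes. When the correlation was estimated, 0 of the 11 held (3 lists at an unadjusted p under 0.05). For histones and the integrated stress response the estimates, -0.026 and -0.00553, lay below the preset 0.01, and the calls were still lost. A higher correlation was therefore not the reason for these losses, and what else differs in that form of the test was not examined. The test fry, which does not compare a list with other genes, called 26.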

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

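The fits without the 50 most abundant genes, with length or GC offsets and without DDR2 were chosen after seeing the data. The count of called genes, 12076, ranged from 9904 (stricter filter, fewer genes tested) to 13625 (no filter, more genes tested), was 11739 with DESeq2 and 12108 with limma-voom, and ran from 11915 to 12297 with 1 library left out. Of 48 values of counts under alternatives 46 lay within 1.5 times the main count. The exceptions were the gene lists called, 11 in the main test, 0 with an estimated correlation and 26 with fry, which by construction does not compare a list with other genes. The glycolysis list, with its median of 0.891, lost its call with the estimated correlation (adjusted p = 0.559), and over the camera fits with the preset correlation its adjusted p ran from 0.00039 to 0.0268. Of 1243 values of named genes 1238 kept their direction and call, 5 kept the direction without the call (PKM, LDHA and ESAM with library totals, LDHA and MITF with a GC offset) and 0 changed direction. Of 406 values of lists 364 kept both, 14 lost and 24 gained a call, and 4 changed the direction of the test, none of them a call. Nuclear oxidative phosphorylation turned down with library totals (median -0.334) and in the lowest of the fits with 1 library left out (median -0.104, without curcumol replicate 1; the highest was 0.003). The mitochondrial genome list turned down with a length offset (median -0.09) and a GC offset (median -0.115). The cause was not tested. With the replicate number as a block 12086 genes passed, and the NF-kB list missed the threshold (camera adjusted p = 0.0501). Deviations of libraries with the same number correlated at 0.0238, -0.0123 and 0.0751, so the numbers do not pair the samples. In simulated data with 200 genes set to change, 65.3% of 1.5-fold changes were recovered, a share not split by count level.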

Other observations

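The gene groups in this paragraph and the next were chosen after the data were seen, as were the test of S phase genes, the length and GC offsets, the fit without abundant genes, and the GC, scaling and resampling checks of zinc finger genes. Subunits of the proteasome, which degrades ubiquitin-tagged proteins, were higher in curcumol, with 30 of 31 tested genes risen and 0 fallen, and 29 risen and 1 fallen with library totals. The median log2 fold change was 1.14 (camera adjusted p = 4.41e-09, and adjusted p = 0.18 with an estimated correlation). Camera p-values in this paragraph and the next were adjusted over the added groups and the zinc finger genes, not over the fixed lists. They describe groups picked from the same data and are no independent support. PSMC4 (2.02) and PSMA6 (1.98) were among the highest proteasome subunits. The interferon-induced subunits PSMB8 (-1.25) and PSMB9 (-1.55), which replace standard ones in the immunoproteasome, fell. Among 14 genes of class I antigen presentation 7 rose and 6 fell (camera adjusted p = 0.56). HLA-B (1.72), HLA-C (1.42), HLA-E (1.88) and B2M (1.11) rose, while NLRC5 (-3.28), a transactivator of these genes, fell. HLA genes share reads and differ between cell lines and the reference, so their values are uncertain.

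Of 19 genes of homologous recombination and the Fanconi pathway, which repair broken and crosslinked DNA, 16 fell and 2 rose (median -1.15, camera adjusted p = 0.00126, and adjusted p = 0.18 with an estimated correlation). FANCF (-3.61) and XRCC2 (-2.37) fell most. Of 6 metallothionein and zinc export genes 4 fell and 1 rose (camera adjusted p = 0.15), with MT1M at -3.39 and MT2A at -1.60. Of 20 aminoacyl-tRNA synthetase genes 10 fell and 6 rose (camera adjusted p = 0.255), against 14 and 2 with library totals and 13 and 6 with a GC offset. Host genes of small nucleolar RNAs had 11 of 18 higher and 6 lower (camera adjusted p = 0.151), with ZFAS1 at 2.48 and GAS5 at 1.65. DUSP4, a MAP kinase phosphatase gene of the immediate early list, had 0, 1 and 0 counts in control and 42, 43 and 27 in curcumol.

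Most tested genes changed between the groups. Without the 50 most abundant genes 12054 genes passed, but TMM already scales for such genes, so that fit cannot decide. Counts taken by a few abundant genes would lower the others, yet 4818 genes were higher under scaling by library totals. This argues against a few abundant genes as the whole cause. Trends with exon length or GC content are argued against in the same sense, with 12114 and 12036 genes called under these offsets. The GC offset, however, ended 1470 calls and turned 380. The length offset used the joined exons of each gene, so it does not cover a trend with transcript length. Of the 10 splits of the libraries into 3 and 3 only the real one, 1 split, gave 12076 genes, and the highest other gave 0 by edgeR (48 at an unadjusted p under 0.05, against 12225), but 10 splits are too few for a share under 0.05. An effect of curcumol, or any other difference between the cultures that went with treatment, stays open.

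Ribosomal protein mRNAs rose relative to other genes by camera with a preset correlation, a call that was lost with an estimated correlation (adjusted p = 0.47 with an estimated correlation). Their lower quartile stayed at 0.67 with a GC offset, against a GC trend as the whole cause. With a length offset it stayed at 0.72. That offset used all annotated exons of a gene joined (8153 bases for RPL37). It therefore cannot decide on a trend with the length of the mRNAs themselves. A candidate explanation is lower nuclear transcription, with long-lived mRNAs taking a larger share, which predicted a fall of the short-lived mRNAs of numbered zinc finger genes. The median of 382 such genes was 0.78 (bootstrap interval 0.62 to 0.93, genes taken as independent), 0.62 with a GC offset and 0.51 with library totals, which goes against it for this class. Reads shared with processed pseudogenes were not separated, and a change in transcription or stability of these mRNAs stays untested.

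Histone mRNAs that mostly lack a poly(A) tail rose, from 779 to 6615 counts over the 11 tested genes, while 8 untested ones held 80 and 81. A GC trend is argued against by a lower quartile of 2.89 with the offset. More cells in S phase predicted a rise of the S phase list, whose median was -1.20 and upper quartile -0.61. This goes against it only as far as mRNA of these genes follows the share of cells in S phase, which was not measured. More RNA without a tail carried through selection cannot be told apart from a change in the cells, because RN7SL2 was the only such RNA tested (-1.04, edgeR adjusted p = 0.077). Histone transcripts that carry a tail may also account for the rise, and were not tested because counts per gene do not show transcript ends.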
